A study of Mus musculus with 2 samples.

How the data were processed

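Interscapular brown adipose tissue, the thermogenic fat depot between the shoulder blades, was taken from C57BL/6J male mice aged 1 month. The labels give 2 groups. In the first, Rheb had been deleted in the adipocyte lineage by crossing a floxed Rheb allele with a Cre transgene driven by the Fabp4 promoter. The second consisted of control littermates. Rheb is a small GTPase that activates the kinase complex mTORC1. Tissue from 3 mice was pooled for each genotype, and each pool gave 1 array, so the comparison rests on 2 arrays with no replicate array in either group. The spread between animals is hidden inside the pools.

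Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy3 by Agilent's one-colour low-input kit. Per the submitters' processing notes, Agilent Feature Extraction 10.7 and limma were used. The notes as held here give neither the role nor the order of these tools. The background correction, the treatment of repeated spots and the normalization are not given in the sources used here. The deposited table holds 1 log2 intensity per probe ID and array. Its unit was read from the values, which ran from 1.25 to 18.4 on both arrays. When the values of each array were sorted, the 2 lists differed by a median of 0.0036 log2 units and by at most 0.359. Such nearly equal distributions are what quantile normalization leaves, and a normalization of this kind removes any change in the overall level of the array. Scanner files, detection flags and spot-level values were not used here, so precision is limited by the number of arrays, and a probe's own measurement error is unknown.

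The table held 56745 IDs with no missing value. Of these, 56605 were probes whose IDs begin with the letter A and a series number, and 140 were control IDs. The table pairs no probe ID with a gene, and 0 of the probe IDs occurred in the gene table supplied with the series. Results are therefore given per probe and not per gene. Rheb, Fabp4 and Ucp1 could not be looked up, so the labels were not checked against the deleted gene. The 50 gene lists with 1236 symbols that had been fixed before the data were examined, covering brown fat metabolism, mTORC1 and cAMP signalling, inflammation and the markers of other cell types, were not analysed here. For the same reason neither the planned combination of probes per gene nor the planned spread over probes of 1 gene was computed. The rule for named genes, which asked for the 12 highest and 12 lowest genes, was replaced by the 2 probes with the highest and the 2 with the lowest difference, because an ID alone says nothing of the target.

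The difference for each probe was the knockout value minus the control value on the log2 scale. Control IDs were left out. Probes were kept when their mean over both arrays was at or above the median of all probe means, 3.99, which left 28303 probes. A size rule of 1 log2 unit, or 2-fold, was fixed before the data were examined. With 1 array per group no p-value was computed. The local spread of the differences was taken as 1.4826 times the median absolute deviation in 10 bins of mean intensity with nearly equal numbers of probes. This local spread contains real differences between the genotypes as well as array error. Exact (Clopper-Pearson) 95% binomial intervals accompany shares of probes. They cover counting error only and treat probes as independent, although several probes can share a gene.

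The 96 control IDs named ERCC, after a set of synthetic spike-in RNAs, lay near the bottom of the scale and served as a measure of background. The bound was set at their 95th percentile on each array, which was 2.09 on the control array and 1.94 on the knockout array. Where the dimmer value of a named probe was at or below this bound, the difference is given as a lower bound against it. The bright control probes were those with names starting E1A, Agilent's one-colour spike-in RNAs, or DCP and a mean of at least 4.

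Alternatives chosen before the data were examined were no filter, a filter at the 75th percentile of probe means, centring on the median difference, quantile normalization with limma 3.58.1, a loess correction of the difference on the mean with a span of 0.3, and size rules of 1.5-fold and 3-fold. Added after seeing the data were centring on the bright control probes, a rule of 2-fold plus 3 local spreads, a filter that asked for both values above the background bound, and the kept probes with values below that bound raised to it. Standard errors of the bin medians came from 1000 bootstrap draws of probes. The calculation was tested on simulated data made for the knockout against control comparison from the deposited probe means, with Gaussian scatter of the local spread and known changes in 2 sets of 100 probes. For the simulation the local spread was taken in bins of all probes rather than of the kept ones. The calculation recovered 97% of the 100 probes changed by 4-fold and 100% of the 100 probes changed by 8-fold. The changed probes were drawn from a brighter set than the kept probes, and no 2-fold change was simulated. Recovery near the 2-fold rule is therefore unknown. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3.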

Results

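The study asked which transcripts differ in brown adipose tissue when Rheb is removed from the adipocyte lineage. One-colour Agilent arrays measured RNA from 1 pool of 3 knockout mice and 1 pool of 3 control littermates. Each array gave a normalized log2 intensity for 56605 probes. The median was 4.05 on the control array and 4.06 on the knockout array, and the 75th percentiles were 7.35 and 7.36. At or below the background bound lay 34.4% of the probes on the control array and 33.2% on the knockout array. There was no replicate array, so none of the differences below could be set against the spread between animals, and none carries a p-value. The table gives probe IDs without gene names, so the differences are those of probes, and the change in Rheb itself was not analysed here.

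Most probes had similar intensities in both pools. Across all 56605 probes, which are not independent replicates, the arrays had a Pearson correlation of 0.977 and a Spearman correlation of 0.945. Of the 28303 probes kept by intensity, 25225, or 89.1%, differed by less than 2-fold. The kept probes had a median difference, knockout minus control, of -0.05 log2 units, and their 5th and 95th percentiles were -0.99 and 1.11. The local spread narrowed with intensity, from 0.73 log2 units in the dimmest of 10 bins of kept probes to 0.41 in the brightest. The share of probes at least 2-fold apart fell along with it, from 20.2% in the dimmest bin to 3.60% in the brightest.

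**Figure D1:**
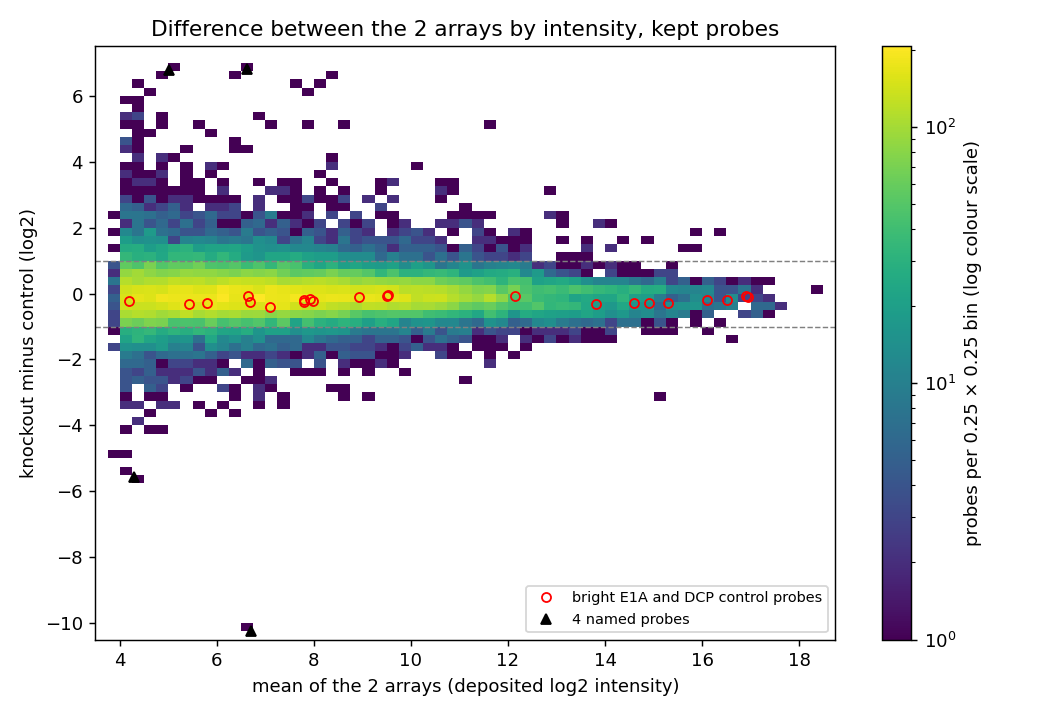
Difference between the knockout and control arrays (log2, vertical axis) against the mean of both arrays (deposited log2 intensity, horizontal axis) for the 28303 kept probes, coloured by the number of probes per bin on a log colour scale. Dashed lines mark 2-fold, open circles are the 22 bright E1A and DCP control probes and triangles are the 4 named probes; the scatter narrows toward bright probes, and more probes lie far above the upper line than far below the lower one.

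In the knockout pool 1714 kept probes were at least 2-fold higher and 1364 were at least 2-fold lower than in the control pool, together 10.9% of the kept probes. The median difference was 1.40 log2 units among the higher probes and -1.34 among the lower ones. The dimmer value was at or below the background bound for 22 of the higher and 5 of the lower probes, whose measured folds are therefore uncertain. All of these probes were at least 16-fold apart, which the filter on the mean nearly fixed in advance. In simulated arrays with Gaussian scatter of the local spread, 935 unchanged kept probes passed the 2-fold rule upward and 909 downward. That scatter was scaled to these same differences, so it holds any real difference between the genotypes. The simulated counts are therefore not an estimate of array error alone. When a probe had to lie beyond 3 local spreads as well, 590 higher and 369 lower probes remained.

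Probes higher in the knockout pool outnumbered lower ones among the larger differences. They made up 55.7% of probes at least 2-fold apart (95% binomial interval 53.9 to 57.5%). At 4-fold they were 356 of 542 probes, or 65.7% (61.5 to 69.7%). At 8-fold they were 107 of 142, or 75.4% (67.4 to 82.2%), and at 32-fold 28 of 31, or 90.3% (74.2 to 98.0%). Of those beyond 32-fold, 14 higher and 3 lower probes had a dimmer value at background. At 16-fold this held for 22 of 49 higher and 5 of 8 lower probes, so the shares at the largest folds rest in part on values at background. With values below the background bound raised to it, 20 higher and 2 lower probes were at least 32-fold apart. The counts at 8-fold were again 107 and 35, but the filter on the mean fixed this in advance. A kept probe at background in 1 pool must be bright in the other, so raising cannot bring it under 8-fold. At 1.5-fold there was no such excess, with 3929 higher and 4064 lower probes. In the brightest of the 10 bins the 2-fold probes were evenly divided, with 51 higher and 51 lower.

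The lowest deposited difference belonged to probe A_30_P01023652, which had a log2 intensity of 11.84 in the control pool and 1.59 in the knockout pool. The knockout value was at background, so the signal was at least 953-fold lower in the knockout. The probe listed next, A_66_P135146, read 7.07 in the control pool and 1.499, again at background, in the knockout pool, which is at least 35.0-fold lower. The highest deposited differences belonged to A_51_P479715 and A_51_P238557, whose order is open because one of them was at background in the control pool. Probe A_51_P479715 was at 3.21 in the control pool and 10.03 in the knockout pool, a difference of 6.81 log2 units with both values above the background bound. Probe A_51_P238557 read 1.63, at background, in the control pool and 8.40 in the knockout pool, which is at least 79.6-fold higher in the knockout. Taken against the background bound, these differences were at least 7.07 to 18.5 times the local spread at each probe's mean intensity. Each rests on a single value per array.

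The control probes had a small common offset between the arrays. All 8 bright E1A spike-in probes were lower on the knockout array, by a mean difference of -0.18 ± 0.10 log2 units (SD over probes). The 14 bright DCP probes had a mean difference of -0.22 ± 0.10, and all 14 were lower. The DCP and E1A probes are not independent sets. DCP_1_0 read 17.01 on the control array beside 16.95 for the E1A probe with number 1, and DCP_22_0 read 9.55 beside 9.55 for the E1A probe a22. All 22 together had a mean of -0.21, against the median of -0.05 for the kept tissue probes. If the bright control probes rather than the deposited scale are set to no difference, every tissue probe shifts upward by 0.21 log2 units. The 2-fold probes then number 2568 higher and 877 lower, so that 74.5% were higher instead of 55.7%. This holds only if both pools received the same amount of spike-in RNA, which was not checked.

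**Figure D2:**
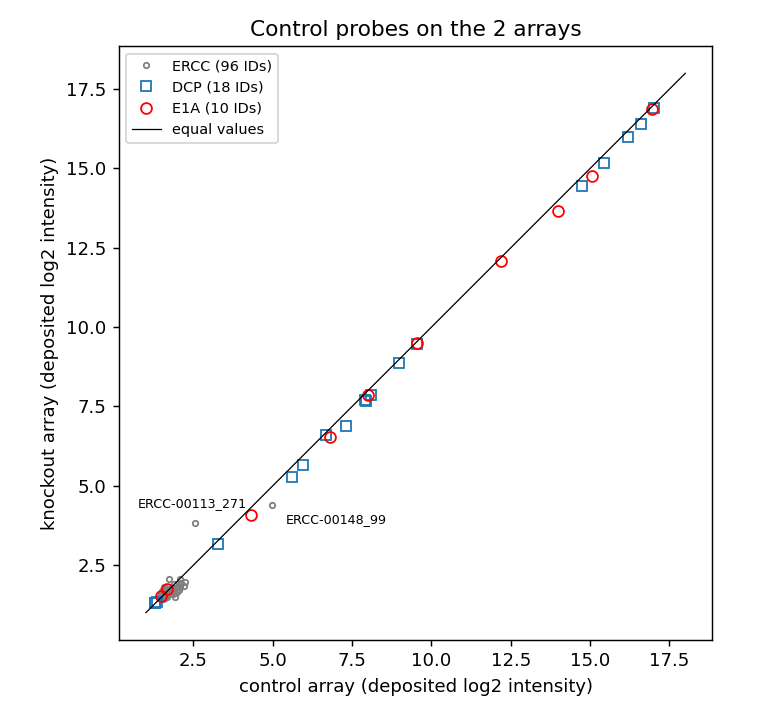
Deposited log2 intensity of control probes on the control array (horizontal axis) and the knockout array (vertical axis), 1 point per ID, with the line of equal values. The bright E1A (circles) and DCP (squares) probes lie slightly below the line, and all but 2 of the 96 ERCC probes (small points) cluster at background.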

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

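All of the tests in this part were chosen after the values had been seen. The same 2 ERCC control probes carried signal beyond a fence on both arrays. The fence lay 3 interquartile ranges above the upper quartile of the 96 ERCC probes, which otherwise served only to set the background bound. ERCC-00148_99 read 4.38 on the knockout array and 4.96 on the control array. ERCC-00113_271 read 3.82 on the knockout array and 2.56 on the control array. An ERCC spike-in mix added to the RNA would raise many of these probes above background, but 1 of the 96 lay at least 1 log2 unit above the DarkCorner control on both arrays, which argues against such a mix. Binding of tissue RNA by these probes, to a different extent in the pools, may remain as an explanation and was not tested.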

How the results depend on the processing

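The settings of the first 7 alternatives below were fixed before the data were examined and the last 4 were added after seeing them. Counts are of probes at least 2-fold higher and lower in the knockout pool (1714 and 1364 as reported, 55.7% higher). Without the intensity filter there were 4159 and 3746 (52.6%). With the filter at the 75th percentile there were 552 and 422, at a similar 56.7%. Centring on the median difference moved the share to 59.9% and the loess correction to 60.2%; since the medians are below 0, both can only raise it. Quantile normalization left 1708 and 1362 probes, and since it moved the kept differences by a median of only 0.0062 log2 units, it says little. A size rule of 3-fold gave 640 and 402 (61.4%), and 1.5-fold gave 3929 and 4064, where the share turned to 49.2%. Centring on the bright control probes left 877 lower probes and raised the share to 74.5%. The rule of 2-fold and 3 local spreads gave 590 and 369 (61.5%). Requiring both values above the background bound, which admits dimmer probes and drops those at background in either pool, gave 2261 and 2128 (51.5%). Among the kept probes alone, 1692 higher and 1359 lower ones had both values above the bound. The fall in share thus came with the added dimmer probes. The bound was also higher on the control array (2.09) than on the knockout array (1.94), which by construction drops higher probes more readily. Raising values below that bound to it left 1714 and 1364, which the filter on the mean fixed in advance. The 4 named probes moved by at most 0.21 log2 units, too little for these settings to test their direction. The cause of these shifts was not tested beyond what each setting does by construction. No paired analysis was possible because each group has 1 array. No array could be left out for the same reason, and the average over probes of a gene was not run because the probes are unnamed. Without detection flags, signal over background was judged from control probes alone.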

Other observations

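The tests in this part were chosen after the values had been seen, except the 2-fold rule, the 75th percentile filter and the loess correction. Large differences ran mostly one way, with 107 probes at least 8-fold higher and 35 at least 8-fold lower in the knockout pool, and 55.7% of all 2-fold probes higher. An upward shift of the whole knockout array would have raised its control probes, whose mean difference was -0.21 log2 units. The amount of spike-in RNA added to each pool was not checked, so this offset alone cannot exclude a shift. The nearly equal distributions of the deposited values leave little room for such a shift in any case. An intensity trend that moved most probes of a bin upward would need a median difference above 0 in that bin. The highest of the 10 bin medians was -0.032 with a bootstrap standard error of 0.016. The nearly equal distributions hold the differences near 0 as a whole, and a trend in spread needs no median above 0. The bin medians therefore decide little. Under the loess correction the share was 60.2%. With medians below 0 that correction could only raise the share, so it does not test the trend. Scatter of dim probes would leave no excess at or above the 75th percentile of intensity, where the share was 56.7% with an interval of 53.5 to 59.8%, although the brightest of the 10 bins held 51 higher and 51 lower probes. The nearly equal distributions argue against a shift of the whole array as the whole cause of the 2-fold excess. The share at or above the 75th percentile argues against scatter of dim probes as its whole cause, though the interval holds counting error only. An intensity trend stays open. The excess at 8-fold was not counted at or above the 75th percentile, so scatter of dim probes stays open there. An effect of the normalization itself stays open, since the sorted values differed by a median of 0.0036 and values from before that step were not used here. A loss of Rheb, a difference between the pooled animals, and other tissue carried along in 1 pool all may produce such an excess and cannot be separated with 1 pool per genotype and no gene names.

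Probe A_30_P01023652 was at least 9.90 log2 units lower in the knockout pool, against the background bound. That is at least 18.5 times the local spread, beyond the scatter of the bulk of probes at this intensity. The probe was picked for this size as the lowest of 28303 kept probes, and the local spread does not describe rare outliers. A fault of a single spot and a transcript absent from the knockout pool cannot be told apart, since the table holds 1 value of this probe per array. The target of this probe was not analysed here, and a strain or allele difference at it between the pools stays open and untested.

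Across the 6 series of probe IDs, 8 of 12 counts of 2-fold probes lay outside the central 95% of random draws and 4 lay inside. What the series numbers stand for is not given in the sources used here. In series A_65, 63 of 667 kept probes were at least 2-fold higher in the knockout pool, while 10000 random draws of as many probes matched on intensity held 34 to 58 in their central 95%. The same series had 17 lower probes against 25 to 48 in the draws. Series A_30 had fewer differences than its draws in both directions, with 86 higher against 96 to 135 and 73 lower against 77.0 to 111. Series A_51 had 308 lower probes against 224 to 277. Series A_55 had 816 higher probes against 723 to 800, and series A_52 and A_66 had fewer higher probes than drawn, 263 against 266 to 325 and 153 against 155 to 203. The counts inside the draws were the higher probes of A_51, 333, and the lower probes of A_52, A_55 and A_66, with 232, 585 and 149. Probes that share a gene make such draws too narrow, so these are descriptions of the 2 arrays.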
